A study of Mus musculus with 16 samples.

How the data were processed

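Each of the 16 arrays carried a 4C product labelled with Cy5 and genomic DNA cut with the same enzyme labelled with Cy3, per the labels, with no dye swaps. Cells had been fixed in 2% formaldehyde for 10 min, per the labels. The scanner files hold the intensity of each probe in each channel as written by NimbleScan 2.3.18, per the file headers, with no background correction recorded there. The ratio files hold log2 of Cy5 over Cy3 minus the array's Tukey bi-weight mean, per the file headers, which ran from 0.313 to 1.31. Ratio values recomputed from the intensities differed from the deposited log2 values by at most 0.005 at probes with 1 spot. A deposited table of values holds the same log2 values for 26934 probes of chromosome 7. The labels give mm6 for the arrays and mm9 for that table, but its probe names are those of the mm6 design and its values equal those of the ratio files, so its windows were taken in mm6.

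Groups were taken from the sample titles. For the ESC and dESC arrays with MseI, the source name says MboI while the title, the enzyme tag and the second channel say MseI; they were taken as MseI. The protocol texts are the same for all arrays and describe MseI only.

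The design holds 388166 tiling probes and 1193 random control probes. The tiling probes lie in 123 named regions, of which 26 are longer than 300 kb, and in clusters outside them (4305 probes). Random probes were left out of windows and tests, and the 6 probes with more than 1 spot were averaged. The log2 ratio of Cy5 over Cy3 was centred on each array's median and averaged over 5 kb windows with at least 5 probes, which gave 7044 windows, 1601 of them on chromosome 7. Median probes per window were 59 in long regions, 53 in short regions and 7 in clusters. No loess or quantile step was used, since many windows may shift one way. Saturated probes were kept (2 to 181 per array in Cy3 and 6 to 559 in Cy5). Median signals were 765 to 1720 in Cy3 and 1271 to 3260 in Cy5.

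The windows were fitted with limma 3.58.1 (R 4.3.3) as 8 cell-by-enzyme means over all 16 arrays, with 8 residual degrees of freedom and 3.33 prior ones, and p-values were adjusted by Benjamini-Hochberg at 0.05. A cell's value is the mean over its 2 enzymes, and enrichment over genomic DNA also needed a log2 ratio of at least 1. The mean of chromosome 7 minus that of the other chromosomes was compared between cells by an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286. Windows past the threshold within 100 kb were merged into regions. The text names up to 10 regions per direction whose best window separates both arrays of one group from both arrays of the other within each enzyme (for enrichment, all 4 arrays above 0). Where fewer than 5 regions passed, the 5 windows with the smallest p were added to the table of named windows, and the text names some of them. This rule, the tests and the alternatives were fixed before the data were examined, except for those said below to have been chosen afterwards. How the rule reads in 3 respects was settled afterwards: that the best window of a region must pass, that the enzyme comparison is separated within each cell, and that an interaction may be separated in either direction. The limit of 300 kb for long regions and the limits of 1 and 2 for strong windows were also chosen after the data had been seen.

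The procedure was tested on simulated data for dESC against ESC, with 200 of 7044 windows changed. With 1 spread for all groups, 36% of changes of 0.5 were recovered and 100% of those of 1, 2 and -1, and 9 unchanged windows were among 177 calls (5.08%). With each group's own spread, 62%, 100%, 100% and 96% were recovered, and 39 unchanged windows were among 218 calls (17.9%). Adjusted p-values of dESC against ESC are thus too low where the groups differ in spread. Other comparisons, and arrays that differ in spread within a group, were not simulated. A first form of this check, with each group's own spread alone, had missed the limit set for it, and the form with 1 spread was added after that.

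Alternatives were windows of 2 and 20 kb, the median of the probes, normexp with an offset of 50 and loess within arrays (span 0.3). A common median absolute deviation, normal scores, the authors' ratio values and value table, and no minimum of probes were also used. A filter on dim probes left out each probe among the dimmest 10% in Cy3 on any array. It kept 225808 probes and 6746 windows. Others were only the arrays compared with additive terms for cell and enzyme, array weights, the replicate number as a block, each enzyme alone, a threshold of 0.01 and each array left out. Scan dates in the file headers fall into a first batch of 13 arrays and a second of 3 (ESC MboI replicate 1, ESC MseI replicate 1 and PM-Liv MseI replicate 2); the second holds 1 array per group and gives no comparison of its own.

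The primers were matched to NCBIM37 (Python 3.11.15) with gene models of GENCODE M1. That build is not the build of the arrays and no position was converted, so the bait was not placed on the arrays. The planned test of imprinted loci and the planned exclusion of windows within 1 Mb of the bait were therefore not run, and the fixed gene lists were not used. Tables were handled with version 1.17.8 of the R package data.table, and figures drawn with matplotlib 3.10.9 and pandas 2.3.3.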

Results

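Chromosome contacts of the H19 imprinting control region were measured by circular chromosome conformation capture (4C), in which crosslinked chromatin is cut with a restriction enzyme, ligated in dilute solution and amplified outward from a bait sequence. The products were hybridised to tiling microarrays against genomic DNA cut with the same enzyme. There were 16 arrays from 4 kinds of cells. ESC are undifferentiated mouse embryonic stem cells, and dESC are embryonic stem cells kept for 2 weeks without leukaemia inhibitory factor, which keeps such cells undifferentiated. MM-Liv and PM-Liv are neonatal livers, collected 2 days after birth, in which 3 of the 4 CTCF target sites are mutated on the maternally or the paternally inherited chromosome. CTCF is a DNA-binding protein of chromatin boundaries and loops. Each cell was assayed with 2 restriction enzymes, MboI and MseI, on 2 arrays each, which gave 8 groups of 2 arrays. The labels do not state whether the 2 arrays of a group came from separate cultures or animals. The spread in the main limma fit comes from differences between the 2 arrays of each group. If these were not separate cultures or animals, its p-values measure only how well arrays repeat. The number of arrays limits the precision of every value below.

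The median signal of the genomic DNA channel was 1.05 to 5.00 times that of the random control probes, and the median signal of the 4C channel 1.01 to 1.09 times. Most tiled sequence therefore lay near the level of random probes in the 4C channel. The standard deviation of the window log2 ratios ran from 0.14 on dESC MseI replicate 1 and 0.20 on dESC MboI replicate 2 to 0.83 on ESC MseI replicate 2. The same 2 dESC arrays had the lowest genomic DNA signal, 1.05 and 1.12 times that of random probes, against at least 1.30 times on the others. Every dESC value below thus includes an array whose genomic DNA reference lay near the level of random probes. Across windows, which are not independent, the log2 ratios of the 2 arrays of a group correlated at r = 0.43 for dESC MseI, 0.76 for dESC MboI and 0.93 to 0.98 for the other 6 groups.

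The 4 PCR primers given in the labels matched the mouse genome build NCBIM37 at 1 place each, on chromosome 7 between positions 149765211 and 149766889, outside any gene model. The nearest gene model was H19, an imprinted noncoding RNA gene on the minus strand (149761434 to 149764048), whose 5' end lay 1163 bp away. The primers pointed outward from a single MseI fragment of 1699 bp. The 1679 bp from the first to the last primer base held 8 MboI sites (GATC). They include sites inside a nested primer, whose own sequence holds GATC. Whether other primers were used for the MboI arrays is not given in the sources used here. The arrays are in build mm6, so these positions cannot be set beside the window positions below, and genes of the windows are not named.

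The highest window over all 16 arrays lay on chromosome 7, the chromosome of the bait, at 136995000 to 136999999 in mm6. With MboI its log2 ratio was 5.36 ± 0.01 in ESC, 4.69 ± 0.26 in MM-Liv, 4.97 ± 0.25 in PM-Liv and 2.76 ± 0.58 in dESC (SD, n = 2 each). With MseI it was 0.82 ± 0.04, 1.28 ± 0.04, 1.38 ± 0.29 and 0.49 ± 0.40 in the same order. The 8 other windows within 20 kb averaged 2.11 in ESC, 2.22 in MM-Liv, 1.39 in PM-Liv and 0.32 in dESC with MboI, and -0.23, -0.39, -0.58 and -0.23 with MseI. From 20 to 100 kb the MboI mean over 32 windows was 0.75 in ESC, 1.06 in MM-Liv, 0.07 in PM-Liv and -0.17 in dESC. From 100 to 250 kb it was 0.56 in ESC, 0.52 in MM-Liv, 0.19 in PM-Liv and 0.04 in dESC, in the last 2 above their values from 20 to 100 kb. From 250 to 500 kb it was 0.01 in ESC and below 0 in the other cells. No test was made of these distance means, whose windows were chosen after the highest window had been seen.

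**Figure D1:**
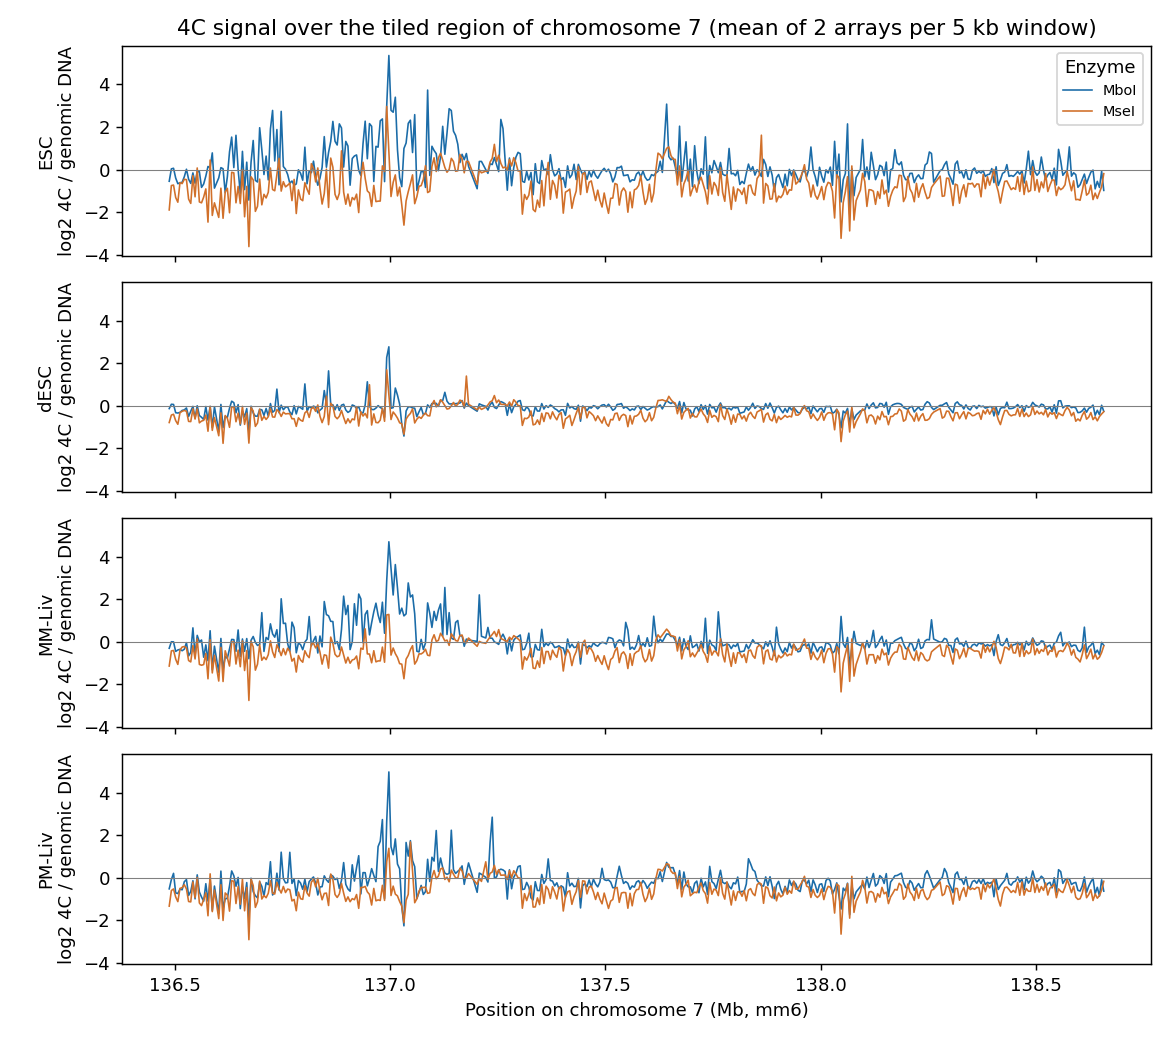
Mean log2 ratio of 4C product over genomic DNA (vertical axis, mean of 2 arrays) along the tiled region of chromosome 7 that holds the highest window (horizontal axis, position in Mb, mm6), per cell, with MboI in blue and MseI in orange. The MboI line peaks at 136995000 in each of the 4 cells, at 5.36 in ESC and 2.76 in dESC.

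The first question was which regions were enriched in the 4C product of each cell. In ESC, 83 of 7044 windows of 5 kb passed the test, 39 of them on chromosome 7. The highest were on chromosome 12 at 72125000 (mean of both enzymes 3.65 ± 0.18 SE), on chromosome 4 at 101180000 (3.40 ± 0.12) and on chromosome 16 at 42995000 (3.40 ± 0.08). Each was far higher with 1 enzyme than with the other: the chromosome 16 window stood at 5.99 ± 0.06 with MboI and 0.80 ± 0.03 with MseI (SD, n = 2), and the chromosome 4 window at 0.73 ± 0.08 with MboI and 6.08 ± 0.48 with MseI. In dESC 12 windows passed, 3 of them on chromosome 7, and 3 of their 11 regions had a best window with all 4 arrays above 0. The first of these was on chromosome 8 at 59925000, with 5.13 ± 0.32 with MboI and 0.37 ± 0.21 with MseI. The others were on chromosome 3 at 153195000 (0.15 ± 0.10 and 4.46 ± 2.35) and on chromosome 7 at 136990000 (2.26 ± 0.04 and 1.68 ± 0.99). In MM-Liv 28 windows passed, led by 136995000 on chromosome 7 and by 109540000 on chromosome 8 (2.57 ± 0.17 SE). In PM-Liv 25 windows passed, led by the same chromosome 7 window, 57945000 on chromosome 6 (3.05 ± 0.25) and 128825000 on chromosome 7 (2.95 ± 0.09). The adjusted p of these windows (limma, Benjamini-Hochberg) was at most 0.00478. Called windows lay on chromosome 7 more often than the tested windows did in ESC (odds ratio 3.06, Fisher's exact test, two-sided, adjusted p = 3.22e-06), PM-Liv (3.70, p = 0.00191) and MM-Liv (2.56, p = 0.0236), and this was not shown in dESC (1.13, p = 0.791). Neighbouring windows are not independent, so these p-values are too small. Without the tiled region of the highest window, a choice made after the data had been seen, the odds ratio was 2.45 in ESC (adjusted p = 0.00414, Fisher's exact test), 2.32 in PM-Liv (p = 0.227), 0.868 in MM-Liv and 0.514 in dESC. Of the called windows, 32 in ESC, 10 in dESC, 19 in MM-Liv and 18 in PM-Liv lay in the small probe clusters outside the named tiled regions, and with clusters left out the counts were 50, 2, 8 and 7. ESC gave 126 windows without ESC MboI replicate 2, dESC 7 without dESC MboI replicate 1, and MM-Liv 16 without MM-Liv MboI replicate 2. With MboI alone limma called 119 windows in ESC, 67 in MM-Liv, 36 in PM-Liv and 16 in dESC. With MseI alone it called 138 windows in ESC, 4 in MM-Liv, 6 in PM-Liv and 0 in dESC, where 4 had an unadjusted p under 0.05. With the scan batch as a block the counts were 64, 9, 28 and 25 for ESC, dESC, MM-Liv and PM-Liv, and 75, 7, 28 and 26 within the first scan batch. When arrays were scaled to a common median absolute deviation they were 31, 16, 45 and 25 in the same order, so ESC no longer had the most.

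**Figure D2:**
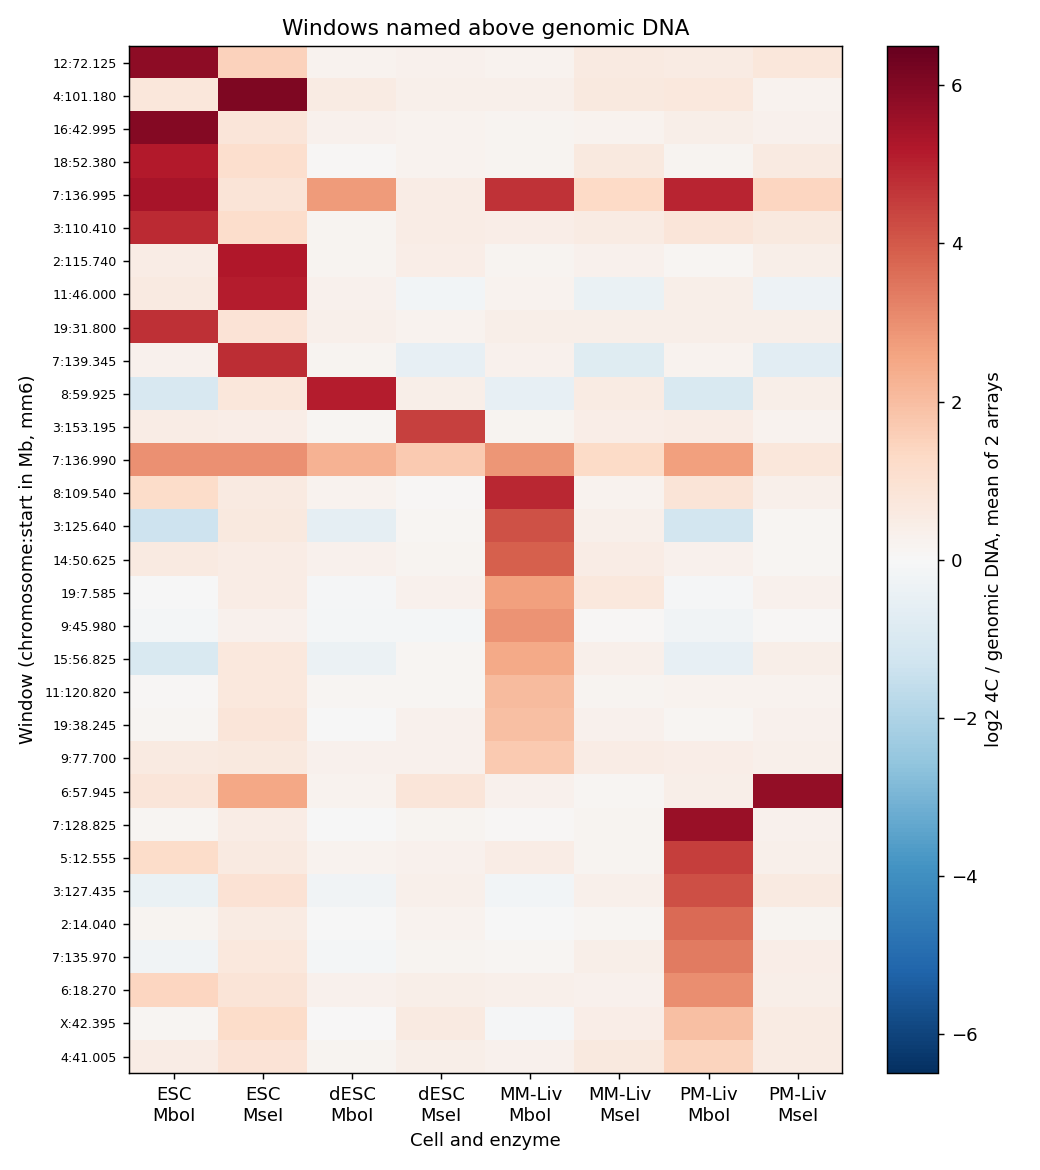
Windows named as enriched over genomic DNA that passed the naming rule (vertical axis, chromosome and start in Mb, mm6) in each cell and enzyme (horizontal axis). Colour gives the mean log2 ratio of 2 arrays: the window of chromosome 16 at 42995000 is at 5.99 in ESC with MboI and 0.80 in ESC with MseI, while 136995000 on chromosome 7 is above 0 in all 8 groups.

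The second comparison asked how contacts differ after differentiation. The windows with the largest loss in dESC against ESC were those of chromosome 12 at 72125000 (-3.40 ± 0.25 SE), chromosome 16 at 42995000 (-3.16 ± 0.11), chromosome 18 at 52380000 (-2.97 ± 0.20) and chromosome 4 at 101180000 (-2.97 ± 0.17). At 42995000 on chromosome 16 the MboI value was 5.99 ± 0.06 in ESC and 0.26 ± 0.17 in dESC (SD, n = 2). Among regions whose best window separated both arrays of each cell within each enzyme, the largest gains were at 47360000 on chromosome 17 (2.57 ± 0.39 SE) and at 63035000 on chromosome 13 (1.49 ± 0.29). The chromosome 17 window rose from -1.04 ± 0.00061 to 3.36 ± 1.62 with MboI and from -1.30 ± 0.02 to -0.55 ± 0.70 with MseI. limma with Benjamini-Hochberg adjustment called 868 windows lower and 73 higher in dESC, 941 in all, of which 865 had an adjusted p of 0.04 or more. In simulated data with each group's own spread, 17.9% of the calls of this comparison were false at a nominal 5%. That simulation gave both arrays of a group the same spread, while the window standard deviations of the dESC MseI arrays were 0.14 and 0.60. It therefore does not give the false share of the real calls. The total of 941 rests on the edge of the threshold: it was 58 to 122 without any 1 of 14 of the arrays, those of the livers included, 1454 (872 lower, 582 higher) without dESC MboI replicate 1, 4073 (2040 lower, 2033 higher) without dESC MseI replicate 2, and 93 without the 2 dESC arrays of narrow range. With the median of the probes 727 windows were lower and 240 higher. It was 55 with the scan batch as a block, 46 within the first scan batch, 82 with the replicate number as a block, 56 at a threshold of 0.01 and 54 when only these 8 arrays entered the fit. With additive terms for cell and enzyme on the same 8 arrays limma called 0, with 1793 windows at an unadjusted p under 0.05. Fold changes of named windows with adjusted p from 0.0445 to 0.0461 (limma, Benjamini-Hochberg) belong to this edge, such as 6625000 on chromosome 7 (1.38 ± 0.37) and 13285000 on chromosome 18 (1.29 ± 0.36). With the 4C channel alone both had the opposite sign (-0.063 and -0.27). The named higher windows at 5800000, 55490000 and 6220000 on chromosome 7, 3265000 on chromosome 6 and 97635000 on chromosome X reversed as well. These gains were thus not seen in the 4C channel, where limma called 9 windows higher and 159 lower in dESC.

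The third comparison set livers with the mutation on the paternal chromosome against livers with it on the maternal chromosome. PM-Liv was higher at 127435000 on chromosome 3 (2.33 ± 0.18 SE) and at 18270000 on chromosome 6 (1.41 ± 0.21). These were the 2 regions whose best window had both arrays of PM-Liv above both of MM-Liv with each enzyme. PM-Liv was lower at 125640000 on chromosome 3 (-2.76 ± 0.19), 50625000 on chromosome 14 (-1.98 ± 0.12) and 7585000 on chromosome 19 (-1.58 ± 0.23), the 3 such regions in that direction. Most of each difference came from MboI: at 127435000 the values were 4.21 ± 0.51 in PM-Liv and -0.18 ± 0.23 in MM-Liv with MboI, and 0.60 ± 0.14 and 0.34 ± 0.19 with MseI (SD, n = 2). Of the windows that did not pass that rule, 128825000 on chromosome 7 was higher (2.83 ± 0.13 SE) and 63930000 on chromosome 5 lower (-2.85 ± 0.13) in PM-Liv, each with a single enzyme. limma called 55 windows, 23 higher and 32 lower, and their adjusted p at the 5 regions named first was at most 0.00549. The count was 92 without either MseI array of dESC, 44 with the scan batch as a block, 24 within the first scan batch, 7 with MseI alone, 8 with probe clusters left out, 81 when only these 8 arrays entered the fit and 1 when that fit had additive terms for cell and enzyme. With arrays scaled to a common range the split became 26 higher and 78 lower.

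The fourth comparison set the livers against the embryonic stem cells, which differ in tissue, strain and genotype together. In no called region did the best window have every liver array on the same side of every stem cell array within each enzyme. The windows with the smallest p-values were high in 1 of the 8 groups: 146640000 on chromosome 1 was lower in livers by limma (-1.77 ± 0.07 SE) and stood at 6.22 ± 0.11 in ESC with MboI, against 0.13 ± 0.08 in dESC (SD, n = 2). In the other direction 63930000 on chromosome 5 (1.70 ± 0.09 SE) stood at 5.48 ± 0.14 in MM-Liv with MseI and at -0.15 ± 0.06 in PM-Liv. limma called 89 windows, 39 higher and 50 lower, a count of 69 with the scan batch as a block, 40 within the first scan batch, 27 after the filter on dim probes and 14 with probe clusters left out. It was 0 when liver or stem cell and enzyme were the terms of the limma fit, which counts differences between cells of the same kind as spread, and 52 windows then had an unadjusted p under 0.05.

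The enzyme comparison covered the largest number of windows. MseI values lay below MboI values at 13435000 on chromosome 18 (-3.79 ± 0.21 SE) and at 136995000 on chromosome 7 (-3.46 ± 0.13), and above them at 137540000 on chromosome 1 (1.83 ± 0.11) and 13015000 on chromosome 18 (1.60 ± 0.12). At 13435000 on chromosome 18 the values were -4.34 ± 0.21 in ESC with MseI and -0.12 ± 0.03 with MboI (SD, n = 2). limma called 4148 of 7044 windows, 2045 higher and 2103 lower with MseI, and 3919 with the scan batch as a block and 2910 within the first scan batch. Each enzyme had its own genomic DNA reference. With the 4C channel alone the count was 195, 36 higher and 159 lower, and the value at 13435000 on chromosome 18 was 0.019, so the difference there lay in the reference.

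Windows that depended on the enzyme were tested as interactions. For dESC against ESC, 91 windows differed between enzymes, 73 of them with a higher difference with MseI than with MboI. They included 109350000 on chromosome 7, at 5.68 ± 0.03 in ESC and 0.13 ± 0.24 in dESC with MboI and at -0.03 ± 0.26 and 0.18 ± 0.03 with MseI (interaction 5.76 ± 0.21 SE). Of the 73 windows, 55 lay on chromosome 7. Without the tiled region of the highest window, 24 windows were higher and 15 lower. The count was 1502 (981 higher, 521 lower) without dESC MseI replicate 2. For PM-Liv against MM-Liv, 49 windows differed, 27 higher and 22 lower, but 79 and 27 with a common median absolute deviation, 63 and 30 with normexp and 38 and 8 with normal scores, and 7 windows with probe clusters left out. The interaction was 6.12 ± 0.57 SE at 178895000 on chromosome 2 and -4.66 ± 0.34 at 139485000 on chromosome 7. Without either MseI array of dESC the count was 76. Counts were 82 and 44 with the scan batch as a block and 49 and 22 within the first scan batch.

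Windows at a log2 ratio of at least 1 on both arrays of a group numbered 84 in ESC, 14 in dESC, 62 in MM-Liv and 32 in PM-Liv with MboI, and 64, 2, 5 and 6 with MseI. On chromosome 7, ESC and MM-Liv shared 16 such MboI windows where 1.60 would be shared by independent lists, ESC and PM-Liv 10 against 0.748, and MM-Liv and PM-Liv 8 against 0.590. On the other chromosomes, the 12 pairs of cells with the same enzyme shared 5 windows in all, of 83 possible and 0.332 expected. There the 2 enzymes of a cell shared 4 windows of 35 possible and 0.202 expected, all 4 in ESC, and groups differing in cell and enzyme shared 0 of 62. These expected numbers take all windows as alike and are too low. Summed over groups, 77 of the 110 such windows there lay in probe clusters, which held 86 of the 5443 windows. On chromosome 7 neighbouring windows are not independent.

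**Figure D3:**
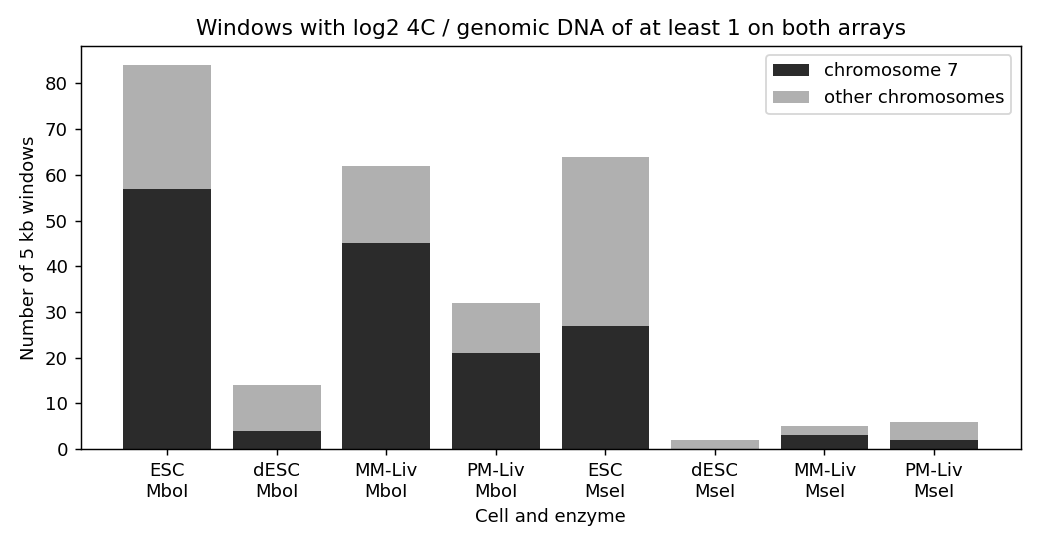
Number of 5 kb windows (vertical axis) with a log2 ratio of at least 1 on both arrays of each cell and enzyme (horizontal axis), on chromosome 7 (black) and on other chromosomes (grey). ESC with MboI had 84 and dESC with MseI 2.

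As a single value per array, the mean of chromosome 7 minus that of the other chromosomes was 0.06 ± 0.13 in ESC, 0.02 ± 0.04 in dESC, 0.07 ± 0.10 in MM-Liv and 0.06 ± 0.09 in PM-Liv (SD, n = 4). The difference was -0.042 for dESC against ESC (exact permutation test, two-sided, p = 0.514) and -0.0062 for PM-Liv against MM-Liv (exact p = 0.914). Neither passed 0.05. For dESC against ESC the enzymes gave opposite signs: with MboI the value was 0.05 ± 0.03 in dESC and 0.17 ± 0.01 in ESC, and with MseI -0.01 ± 0.03 and -0.06 ± 0.01 (SD, n = 2). Within an enzyme the arrays of the 2 cells did not overlap, but 6 arrangements allow no exact p under 0.333. The pooled test averages these differences and counts the enzyme difference as spread. By group the value was 0.05 to 0.17 with MboI and -0.06 to -0.01 with MseI.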

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

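The tests of one amplified product, of a contact seen with both enzymes and of a dim reference, and the limit of 1 beside that of 2, were chosen after the results they bear on had been seen, as were the rule that leaving out a liver array voids the test of array range and the form of the counts over other splits of the arrays.

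The difference between dESC and ESC depended on the enzyme in 91 windows, and that between PM-Liv and MM-Liv in 49 windows, each by a test of the interaction itself.

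Windows at a log2 ratio of at least 2 were mostly common to the arrays of a group and not to the other enzyme: outside chromosome 7, 51 of the 68 windows strong on either array of a group were strong on both (75%), and of these the 2 enzymes of a cell shared 0 of 15. At a limit of 1 the figures were 110 of 329 and 4 of 35, and groups differing in cell and enzyme shared 0 of 62. The 15, 35 and 62 are totals of the smaller list of each pair, while the 68 and 329 count windows on either array. Out of the smaller list, the arrays of a group shared 51 of 51 windows at a limit of 2 and 110 of 113 at 1. The 0.202 expected for the 4 of 35 takes all windows as alike and is too low, since strong windows gathered in probe clusters. Both limits were set after the data had been seen. A fragment missing from the other enzyme's genomic DNA is argued against at the limit of 2, since that signal differed by -0.15 log2 units in the median (own minus other enzyme). A cell-specific contact seen with both enzymes stays open: the 4C percentile with the other enzyme, same cell minus other cells, was -0.416 points in the median of the 51 windows (quartiles -9.87 and 7.21, permutation p = 0.984; own enzyme 48.9 to 78.4), but at the limit of 1 the quartiles of the 2 enzymes overlap (-13.4 and 5.74; own enzyme 1.78 and 72.5). Products of amplification shared by both arrays of a group, a contact that 1 enzyme detects, cell type and genotype stay open too, since the labels do not say whether arrays of a group come from separate preparations. Whether other primers were used with MboI is open as well, since 8 MboI sites lie between the primers of the labels, and this was not tested.

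More windows were lower than higher in dESC against ESC (868 and 73). Without the 2 dESC arrays of narrow range, 93 windows were called and 87.1% of them were lower. The excess in that smaller set thus does not rest on those 2 arrays. What made the 868 cannot be told this way, since their number fell as far without a single liver array. The dESC arrays kept also had a lower standard deviation (0.41 with MboI, 0.60 with MseI) than ESC with the same enzyme (at least 0.57 and 0.68). With arrays scaled to a common range the lower windows fell to 8.18% of their number, but leaving out a single liver array, which changes no value of either cell, brought them to 65 to 70, so that test cannot tell range from a threshold edge. The share lower was 83.5% after scaling, but 50.1% without dESC MseI replicate 2, the lowest of the alternatives with at least 20 windows. Differentiation stays open, untested.

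Windows at 2 or more on both arrays of a group were frequent in the small probe clusters outside the named tiled regions: 7.88% of cluster windows times groups against 0.0649% of tiled ones, and all 51 outside chromosome 7 lay in clusters. Fewer probes per window are argued against, since tiled windows thinned to the same probe numbers were strong at 1.21% of the cluster rate. A dim genomic DNA reference is argued against as well, since 97.1% of strong cluster windows also reached 2 in the 4C channel alone on both arrays. Why the clusters were placed on the array is not given in the sources used here, and a choice of sequences from earlier 4C products was not tested.

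Other splits of the same arrays were fitted with a mean per side and enzyme (per side and cell for the enzyme comparison). Each number of splits that gave as many windows includes the real split itself. For dESC against ESC, 5 of 34 splits gave at least the 54 windows of the real one, with 1730 in the highest other. Within MseI that split set dESC MseI replicate 1, the array of the lowest window standard deviation (0.14), against the rest. Within MboI it set ESC MboI replicate 1 against the rest. It points to a structure of the arrays, and chance cannot be excluded. For PM-Liv against MM-Liv, 2 of 34 splits gave at least 81, with 128 in the highest other, and chance cannot be excluded. For livers against stem cells the real split gave 0 by limma (51 at an unadjusted p under 0.05) and 2682 in the highest other of 100 drawn splits, a structure of the arrays. All 100 reach a count of 0, so this says nothing about chance. For the enzymes, 1 of 100 drawn splits, the real one, gave 4148, with 1242 in the highest other. No other drawn split came as high, but only 100 of 4872 possible splits were drawn. The splits also treat the arrays of a group as independent, which the labels do not state, so chance is not excluded. An additive form fitted first gave 0, 1, 0 and 4318 windows by limma for the real splits (1793, 336, 52 and 4584 at an unadjusted p under 0.05) and 34, 2, 100 and 1 splits as large, which says nothing about chance where the real count is 0.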

How the results depend on the processing

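The settings without 2 narrow dESC arrays, with the scan batch as a block, within the first scan batch, with the 4C channel alone, without probe clusters and without the tiled region of the highest window were chosen after the data had been seen; the others before. Counts below are windows beyond 1.5 times the count of the chosen analysis in either direction, which were 83 in ESC, 12 in dESC, 28 in MM-Liv and 25 in PM-Liv over genomic DNA, 941 for dESC against ESC, 55 for PM-Liv against MM-Liv, 89 for livers against stem cells, 4148 for the enzymes, and 91 and 49 for the interactions of dESC and of PM-Liv. Where nothing else is said, the cause of a change was not tested.

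Windows of 2 kb, whose number is larger, gave 299 in ESC, 57 in MM-Liv, 104 for PM-Liv against MM-Liv, 9485 for the enzymes and 146 and 91 for the interactions. Windows of 20 kb, whose number is smaller, gave 33 in ESC, 442 for dESC against ESC, 1079 for the enzymes and 54 for the dESC interaction. The median of the probes gave 152 in ESC. Without a minimum of probes the counts were 999 in ESC, 39 in dESC, 107 in MM-Liv, 201 in PM-Liv, 153 for PM-Liv against MM-Liv, 289 for livers against stem cells and 250 and 142 for the interactions. After the filter on dim probes they were 17, 4, 12 and 8 over genomic DNA, 33 for dESC against ESC, 30 for PM-Liv against MM-Liv, 27 for livers against stem cells, and 52 and 26.

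normexp gave 231 in ESC, 57 in MM-Liv, 101 in PM-Liv, 93 for dESC against ESC, 89 for PM-Liv against MM-Liv and 93 (63 higher, 30 lower) for the PM-Liv interaction. Loess gave 4 in dESC, 56 in MM-Liv, 42 in PM-Liv, 131 for dESC against ESC, 135 (44 higher, 91 lower) for livers against stem cells and 1765 for the enzymes, and a split of 39 higher and 29 lower for PM-Liv against MM-Liv. A common median absolute deviation gave 31 in ESC, 45 in MM-Liv, 85 (14 higher, 71 lower) for dESC against ESC, 104 for PM-Liv against MM-Liv and 106 (79 higher, 27 lower) for its interaction. Normal scores, where a value of 1 is a rank and no log2 ratio, gave 913 in ESC, 577 in dESC, 899 in MM-Liv, 945 in PM-Liv, 42 for dESC against ESC and 50 for livers against stem cells, and the dESC interaction had the opposite sign at 72125000 on chromosome 12 (-0.76) and 31800000 on chromosome 19 (-0.22). The value table, which holds chromosome 7 only, gave 435 windows, so its counts are out of far fewer windows than the others. Its values were not centred on the array's median, and their medians ran from -0.89 to 0.11. It gave 17, 2, 8 and 7 over genomic DNA, 49 for dESC against ESC and 41 for livers against stem cells. For the enzymes it gave 344 (17 higher, 327 lower).

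With only the arrays compared and additive terms for cell and enzyme in place of group means, the counts were 6 in dESC, 0 for dESC against ESC by limma (1793 at an unadjusted p under 0.05), 1 for PM-Liv against MM-Liv and 0 for livers against stem cells (52). With a mean per cell and enzyme the same 8 arrays gave 54 for dESC against ESC and 81 for PM-Liv against MM-Liv, so the additive terms, and not the choice of arrays alone, made the counts this low. Array weights gave 60 for dESC against ESC, 101 for PM-Liv against MM-Liv and 84 for its interaction. The replicate number as a block gave 82 for dESC against ESC; the differences between replicates correlated across groups from -0.83 to 0.88 (median -0.07 over 28 pairs), so the numbers do not pair the arrays. A threshold of 0.01 gave 56 for dESC against ESC and 57 for livers against stem cells.

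With MboI alone the counts were 67 in MM-Liv, 103 for dESC against ESC and 99 for PM-Liv against MM-Liv. Opposite signs were found for PM-Liv against MM-Liv at 137540000 on chromosome 1 (-0.038) and 132035000 on chromosome 7 (0.088), and for livers against stem cells at 63930000 on chromosome 5 (-0.0081), 49995000 on chromosome 5 (-0.23) and 39775000 on chromosome 17 (0.13). With MseI alone the counts were 138 in ESC, 0 in dESC by limma (4 at an unadjusted p under 0.05), 4 in MM-Liv, 6 in PM-Liv, 7 for dESC against ESC, 7 for PM-Liv against MM-Liv and 11 for livers against stem cells. Livers against stem cells had the opposite sign there at 128825000 (-0.089) and 96370000 (-0.044) on chromosome 7 and 166260000 on chromosome 1 (0.19).

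Without the 2 narrow dESC arrays the counts were 93 (12 higher, 81 lower) for dESC against ESC, 95 for PM-Liv against MM-Liv and 76 for its interaction. The scan batch as a block gave 55 for dESC against ESC. Within the first scan batch they were 7 in dESC, 46 for dESC against ESC, 24 for PM-Liv against MM-Liv, 40 for livers against stem cells and 49 and 22 for the interactions. Without probe clusters they were 50, 2, 8 and 7 over genomic DNA, 8 for PM-Liv against MM-Liv, 14 for livers against stem cells, and 45 and 7. Without the tiled region of the highest window they were 36 for PM-Liv against MM-Liv, 58 for livers against stem cells and 39 (24 higher, 15 lower) for the dESC interaction.

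The 4C channel alone gave 49 in MM-Liv, 168 for dESC against ESC, 84 for PM-Liv against MM-Liv, 143 for livers against stem cells, 195 (36 higher, 159 lower) for the enzymes and 103 (74 higher, 29 lower) for the PM-Liv interaction. dESC against ESC then had the opposite sign on chromosome 7 at 6625000 (-0.063), 5800000 (-0.10), 55490000 (-0.13) and 6220000 (-0.081), on chromosome 18 at 13285000 (-0.27), on chromosome 6 at 3265000 (-0.053) and on chromosome X at 97635000 (-0.21). The enzymes did so at 92675000 on chromosome 7 (-0.078), 91280000 on chromosome 17 (-0.042), 122780000 on chromosome 9 (-0.0024), 40440000 on chromosome 3 (-0.034), 3510000 on chromosome 6 (-0.030), 13435000 on chromosome 18 (0.019), 103725000 on chromosome 12 (0.065), 5525000 on chromosome 7 (0.069) and 30395000 on chromosome 6 (0.17).

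With each array left out in turn the counts ran from 56 to 126 in ESC, 7 to 14 in dESC, 16 to 35 in MM-Liv, 21 to 29 in PM-Liv, 58 to 4073 for dESC against ESC, 39 to 92 for PM-Liv against MM-Liv, 61 to 124 for livers against stem cells, 3645 to 4712 for the enzymes, and 72 to 1502 and 36 to 76 for the interactions.

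The difference of chromosome 7 from other chromosomes, PM-Liv against MM-Liv, changed sign with the median of the probes (0.0028), MseI alone (0.0013), the first scan batch (0.023), the tiled region of the highest window left out (0.039), and without MM-Liv MboI replicate 1 (0.013) or 2 (0.032) or PM-Liv MseI replicate 1 (0.017) or 2 (0.023). For dESC against ESC it changed sign without a minimum of probes (0.074) and with MseI alone (0.044). With the tiled region of the highest window left out it was -0.0822 (exact permutation test, p = 0.0857). With each array left out in turn the difference ran from -0.0406 to 0.0322 for PM-Liv against MM-Liv. For dESC against ESC it then ran from -0.0822 to -0.0021. No difference passed an exact p of 0.05, which 6 arrangements of 1 enzyme alone (smallest p 0.333) and 36 within enzymes (smallest p 0.0556) could not reach. Nor could the 15 arrangements of dESC against ESC without the 2 narrow dESC arrays or within the first scan batch. Permutation within enzymes gave p = 0.333 for dESC against ESC and 0.833 for PM-Liv against MM-Liv.

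Of the settings for named windows without leaving out an array, 2022 kept sign and threshold and 274 kept the sign alone. The exclusion of windows within 1 Mb of the bait and the test of imprinted loci were not run, because the bait and the genes were not placed in mm6.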

Other observations

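The 16 arrays were ordered by enzyme more than by cell, and this lay mostly in the genomic DNA channel. Across windows, which are not independent, the genomic DNA signals of arrays of the same enzyme and different cells correlated at a median r of 0.968, and those of different enzymes in the same cell at 0.687. In the 4C channel the medians were 0.292 and 0.252, while the 2 arrays of a group had 0.859.

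Around the highest window of chromosome 7, 8 windows from 136745000 to 137049999 were at a log2 ratio of at least 1 on both MboI arrays in 3 or 4 of the cells, and 2 of them, at 136990000 and 136995000, in all 4. No window outside chromosome 7 was at that level in more than 2 of the 8 groups, where 92 were in a single group and 9 in 2.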
